A study of Homo sapiens with 14 samples.

How the data were processed

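The series is a pooled CRISPR/Cas9 knockout screen of 4 human ovarian clear cell carcinoma lines with the TKOv3 guide library. Per the labels, cells were infected at a multiplicity of infection of 0.3, selected with puromycin for 2 days, sampled at D0 and cultured for 8 doublings. Guides were amplified from 125 µg of genomic DNA. Per the labels, the authors trimmed reads with cutadapt and counted guides with MAGeCK, without stating versions. The deposited table holds counts, the raw number of reads per guide and library, without normalization. It was checked that every value is a whole number and that each of the 14 columns maps to a labelled library.

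The table has 71090 guides under 18054 names, 225 of them with 0 reads in every library. Spreadsheet software had turned 26 gene names into dates. Of these, 1-Mar and 2-Mar each stood for more than one gene, with 8 guides each, and were left out, while the others kept their date-like names. Hyphens that the table held as escape codes were restored in 124 names. Guides with a mean of at least 30 reads over the D0 libraries were kept (70162 guides), a filter that does not look at Final. Genes with at least 3 kept guides were tested, 17604 in all, of which 16564 had 4 guides and 1040 had 3. Gene names are those of the table, and 99.68% of the tested names matched a RefSeq symbol or synonym. Chromosome and gene order came from RefSeq, and since the files name no genome build no coordinates are given. The 142 guides against EGFP, LacZ and luciferase, of which 137 passed the filter, served as controls and were not tested as genes.

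All 14 libraries were fitted in a single model of 8 groups (4 lines at 2 times, 6 residual degrees of freedom) with edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust quasi-likelihood dispersion and a quasi-likelihood F test per guide. The JHOC5 groups hold 1 library each and are assumed to vary like the others. The ranks of the one-sided guide p-values were combined per gene by robust rank aggregation (alpha 0.25) against its exact null, and the gene p is 2 times the smaller of the one-sided p-values, so it is two-sided. Gene p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The gene log2 fold change is the mean over guides of the difference in mean log2 CPM from edgeR (prior count 2), with its standard error over guides. For guides that drop to 0 reads this value depends on the prior count and is no bound. The comparisons were Final against D0 averaged over the 4 lines, the same within OVISE, TOV21G and ES2, and the change in each of these minus the mean change in the other 2. JHOC5 has values and no test. No genome-wide copy number or expression data were used here.

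Gene lists were fixed before the data were examined: 8 of core machinery (cytosolic ribosome, of whose 77 genes 39 could be tested, proteasome, spliceosome, RNA polymerase II, DNA replication, aminoacyl-tRNA synthetases, mitotic machinery, mitochondrial ribosome), 18 chosen for these cells, the olfactory receptors, and the control guides. The 18 include respiratory complex I, mevalonate and cholesterol synthesis, SWI/SNF, positive and negative regulators of PI3K, AKT and mTOR and of RAS and MAPK, the MDM2 group, brakes and drivers of G1, brakes and effectors of Hippo signalling, NRF2 and redox, ovarian clear cell and Mullerian transcription factors, PRC2 and chromatin writers, DNA mismatch and homologous repair, and integrin adhesion. A further list among the 18 was tested and counted but is not described here. Of the 28 lists, 27 were tested with camera (limma 3.58.1) on guides with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The controls were set against olfactory receptor guides by a shift with its 95% rank-based interval.

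The rule for named genes, fixed at the same time, took for the 4-line average the 10 lowest and 10 highest called genes with at least 3 guides going the same way. For each replicated line it took the 6 lowest called depleted in neither other replicated line and the 6 highest called enriched. For each difference between lines it took up to 8 genes in each direction, and for JHOC5 the 5 lowest and 5 highest among genes whose guides all go one way. For core lists it took the 3 lowest members in the 4-line average. For the lists chosen for these cells it took at most 4 called members per list and comparison or, with none called, the 2 largest values. Genes named outside this rule are said to have been chosen after their values were seen.

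Alternatives were DESeq2 1.42.0 size factors, scaling to control guides or to olfactory receptor guides, no guide filter, a minimum of 100 reads, a prior count of 0.5, alpha 1, the DESeq2 Wald test, counts summed per gene, a replicate block, an additive model, fits of a line by itself, leaving out JHOC5 or each library of the other lines, and JHOC5 added to the mean of the other lines. Leaving out TOV21G, or TOV21G and OVISE, and summed counts with their own scaling or their own libraries were added after seeing the data. Simulated counts were drawn at a spread fitted per guide and line, the same at D0 and Final, with that of ES2 used for JHOC5. The pipeline was tested on these data, in which 200 genes were changed (70 by -4, 70 by -2 and 60 by 1 on the log2 scale). For ES2 it recovered 100%, 61.4% and 13.3% of them and for the 4-line average 100%, 82.9% and 38.3%, with 1 to 4 false calls per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.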

Results

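The screen asked which genes ovarian clear cell carcinoma lines need in order to grow. Cas9-expressing cells of 4 human lines, OVISE, TOV21G, ES2 and JHOC5, were infected with TKOv3, a pooled lentiviral library in which each guide RNA directs Cas9 to cut a single gene. Guides were counted by sequencing at day 0 (D0), after selection for infected cells, and after 8 population doublings (Final). Cells that carry a guide against a needed gene are lost from the culture, so the share of reads of that guide drops. OVISE, TOV21G and ES2 had 2 libraries at each time and JHOC5 had 1, which made 14 libraries.

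Total reads per library ran from 20293129 (TOV21G Final replicate 1) to 33611507 (OVISE Final replicate 2). OVISE had 33591228 and 30821189 reads at D0 and 33490902 and 33611507 at Final. TOV21G had 24129802 and 22889414 at D0 and 20293129 and 21658968 at Final. ES2 had 27635106 and 32394726 at D0 and 29527869 and 32847598 at Final, and JHOC5 had 23139218 at D0 and 25323635 at Final. The median guide had between 50 and 367 reads. The libraries differed in evenness. In TOV21G Final replicate 1, 26.9% of guides had fewer than 10 reads, and the 1% of guides with the most reads took 25.1% of all reads. The matching shares were 13.7% and 13.0% in TOV21G Final replicate 2. In JHOC5 D0 the top 1% of guides took 25.5% of reads, against 3.56% to 5.79% in the other 11 libraries. Wilson 95% intervals of these shares of reads reach at most 0.0189 percentage points to either side and cover counting error only. Between replicates, Spearman's rho across guides, which are not independent replicates, was 0.889 at D0 and 0.285 at Final in TOV21G. It was 0.524 and 0.463 in OVISE, and 0.618 and 0.772 in ES2.

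**Figure D1:**
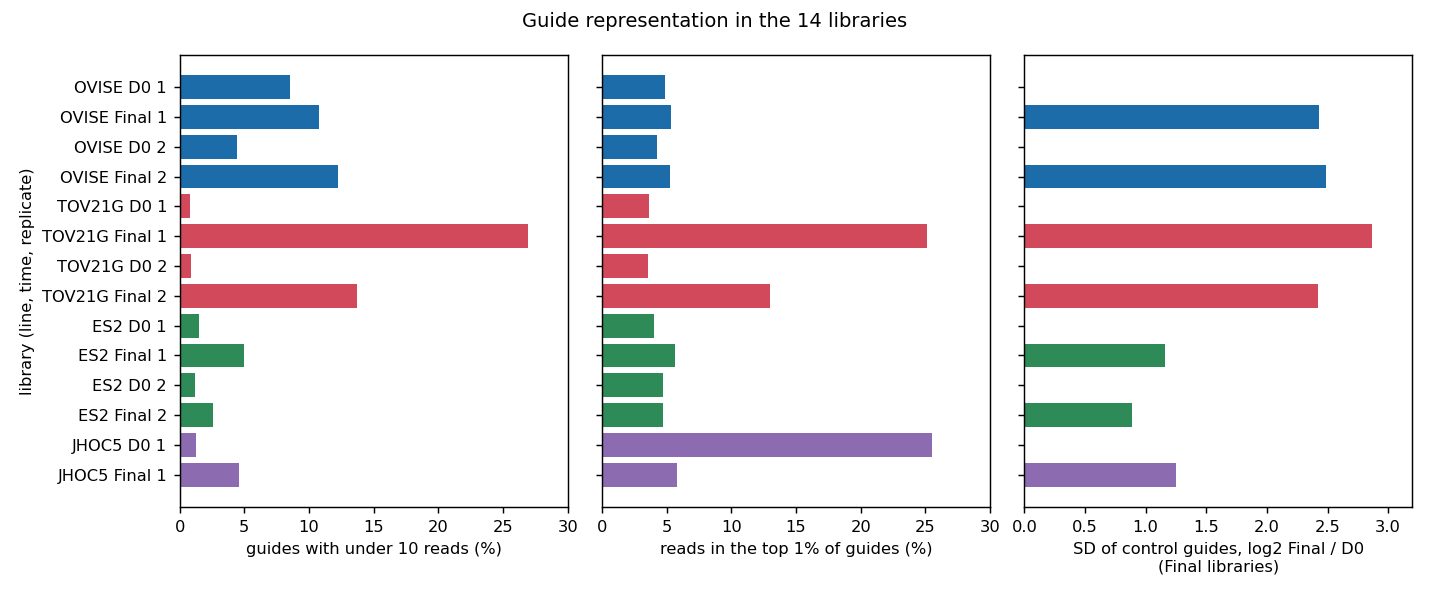
Each bar is 1 library, with the percent of guides under 10 reads, the percent of reads in the top 1% of guides, and, for Final libraries, the standard deviation (log2 units) of the change of the control guides since D0. TOV21G Final replicate 1 stands highest in the share of guides under 10 reads (26.9%), and the control guides spread more in OVISE and TOV21G (2.42 to 2.86) than in ES2 and JHOC5 (0.884 to 1.25).

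Averaged over the 4 lines, knockout of 164 of the 17604 tested genes was depleted between D0 and Final and knockout of 3 genes was enriched. The 10 lowest include genes of protein turnover, DNA synthesis, chromosome segregation and nuclear transport. PSMB7, a subunit of the proteasome core, had the lowest log2 fold change (-5.60 ± 1.04, SE over guides, adjusted p = 0.0372). It was followed by RRM1, the large subunit of ribonucleotide reductase (-5.47 ± 0.28, adjusted p = 0.0209), and COA3, an assembly factor of cytochrome c oxidase (-5.39 ± 0.31, adjusted p = 0.0243). Next came BUB3, a spindle checkpoint protein (-5.35, adjusted p = 0.0184), TCEB2, which encodes elongin B (-5.30, adjusted p = 0.0151), and RAN, the GTPase of nuclear transport (-5.24, adjusted p = 0.0263). DNAJC9, a co-chaperone that handles histones (-5.22, adjusted p = 0.0230), HSPA5, the chaperone of the endoplasmic reticulum (-5.09, adjusted p = 0.0431), and the ribosome biogenesis genes NOP58 (-5.01, adjusted p = 0.0290) and ISG20L2 (-5.00, adjusted p = 0.0320) completed the 10 lowest. All 164 genes had a log2 fold change under 0 in each of the 4 lines. Every Final library lay below every D0 library of its line for 154 of them and above for 0 of the 3 enriched genes. The genes were chosen for this difference, and over all tested genes both Final libraries lay below both D0 libraries in 25.4% in OVISE, 46.7% in TOV21G and 23.8% in ES2 (16.7% by chance), so the count of 154 adds no evidence of its own. The enriched genes changed less. NME8, a thioredoxin-domain protein of cilia, rose by 0.83 ± 0.73 with 3 of 4 guides going up (adjusted p = 0.0431), and TRPM1, a cation channel of the retina, by 0.79 ± 0.08 (adjusted p = 0.0496). The third, KLHL30 (0.60, adjusted p = 0.0492), had fewer than 3 guides going up and is named after its values were seen.

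The median of the called depleted genes was -3.76. The edgeR test found 1242 genes lower and 620 higher at an unadjusted p under 0.05, where 880.2 are expected by chance over both directions. The 164 depleted genes became 47 with control scaling, 86 with olfactory receptor scaling and 67 without JHOC5, and 15 without TOV21G Final replicate 1, 19 without TOV21G Final replicate 2, 17 without OVISE Final replicate 1, 58 without OVISE Final replicate 2, 87 without OVISE D0 replicate 1 and 285 without ES2 Final replicate 2. Of the 29 named calls, those 5 OVISE and TOV21G libraries left 1, 5, 6, 11 and 16 past the threshold when each was left out in that order. The count of 3 enriched genes became 0 without either OVISE Final library, 1 without OVISE D0 replicate 1 or either TOV21G Final library, 5 without TOV21G D0 replicate 2 or ES2 Final replicate 2, 6 without OVISE D0 replicate 2 and 10 without ES2 Final replicate 1. The 10 hold all 3 genes and each set of 5 holds 1, while the 6 and each single gene hold 0 of the 3. None of the 3 was called with guides scaled to the control or olfactory receptor guides.

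Members of the 8 lists of core cell machinery fell as groups in the 4-line average. List medians are given relative to the median of all tested genes, because scaling to the control guides moved that median by -0.58 in the 4-line average, -0.42 in OVISE, -0.37 in TOV21G, -0.66 in ES2 and -0.88 in JHOC5. Scaling to olfactory receptor guides moved it by -0.27, -0.28, -0.23, -0.20 and -0.39 in the same order. DESeq2 size factors moved it by 0.11 in TOV21G, and a prior count of 0.5 by -0.11 there. Of 39 tested cytosolic ribosome genes (relative median -3.30, camera adjusted p = 1.39e-46), 11 fell over all genes tested and 31 adjusted over the list alone, among them RPL10A (-4.90, adjusted p = 0.0391). RPL7 (-5.16) and RPL36 (-4.96) had lower values without passing. Of 32 proteasome genes (-2.71, adjusted p = 1.85e-35), 9 fell and 20 adjusted over the list alone, with PSMA4 at -4.68 (adjusted p = 0.0372) and PSMC6, which did not pass, at -4.67. The spliceosome list (38 genes, -2.14, adjusted p = 3.01e-23) had 4 fallen members and 17 adjusted over the list alone, LSM2 (-4.03, adjusted p = 0.0320) among them, with SNRPA1 (-4.39) and SNRPD2 (-4.11) not passing.

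Of the 11 subunits of RNA polymerase II (-3.07, adjusted p = 2.7e-16), POLR2L fell (-4.23 ± 0.17, adjusted p = 0.0404), 1 over all genes and 8 adjusted over the list alone. POLR2D (-4.15) and POLR2H (-4.13) did not pass. DNA replication (44 genes, -2.28, adjusted p = 3.87e-29) had 5 fallen members and 26 adjusted over the list alone. Besides RRM1 these included CDC45, part of the replicative helicase (-4.20, adjusted p = 0.0230), while POLD3, a polymerase subunit, had -4.04 (adjusted p = 0.0691). Among 20 aminoacyl-tRNA synthetases (-2.08, adjusted p = 2.29e-18), YARS (-4.25, adjusted p = 0.0151) and VARS (-3.63, adjusted p = 0.0492) fell, 2 over all genes and 12 adjusted over the list alone, and FARSB had -3.21 (adjusted p = 0.355). In the mitotic machinery (42 genes, -2.35, adjusted p = 1.05e-28) 4 fell, 27 adjusted over the list alone, including BUB3 and ANAPC4 (-3.92, adjusted p = 0.0419), a subunit of the anaphase-promoting complex to which the uncalled CDC27 (-4.01) also belongs. In the mitochondrial ribosome (72 genes, -1.69, adjusted p = 9.6e-22) 4 fell, 23 adjusted over the list alone, with MRPS16 at -3.91 (adjusted p = 0.0230), and with MRPS14 (-4.38) and MRPL38 (-4.07) not passing. All 8 lists kept an adjusted p of 0.0011 to 0.00216 with an estimated correlation.

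**Figure D2:**
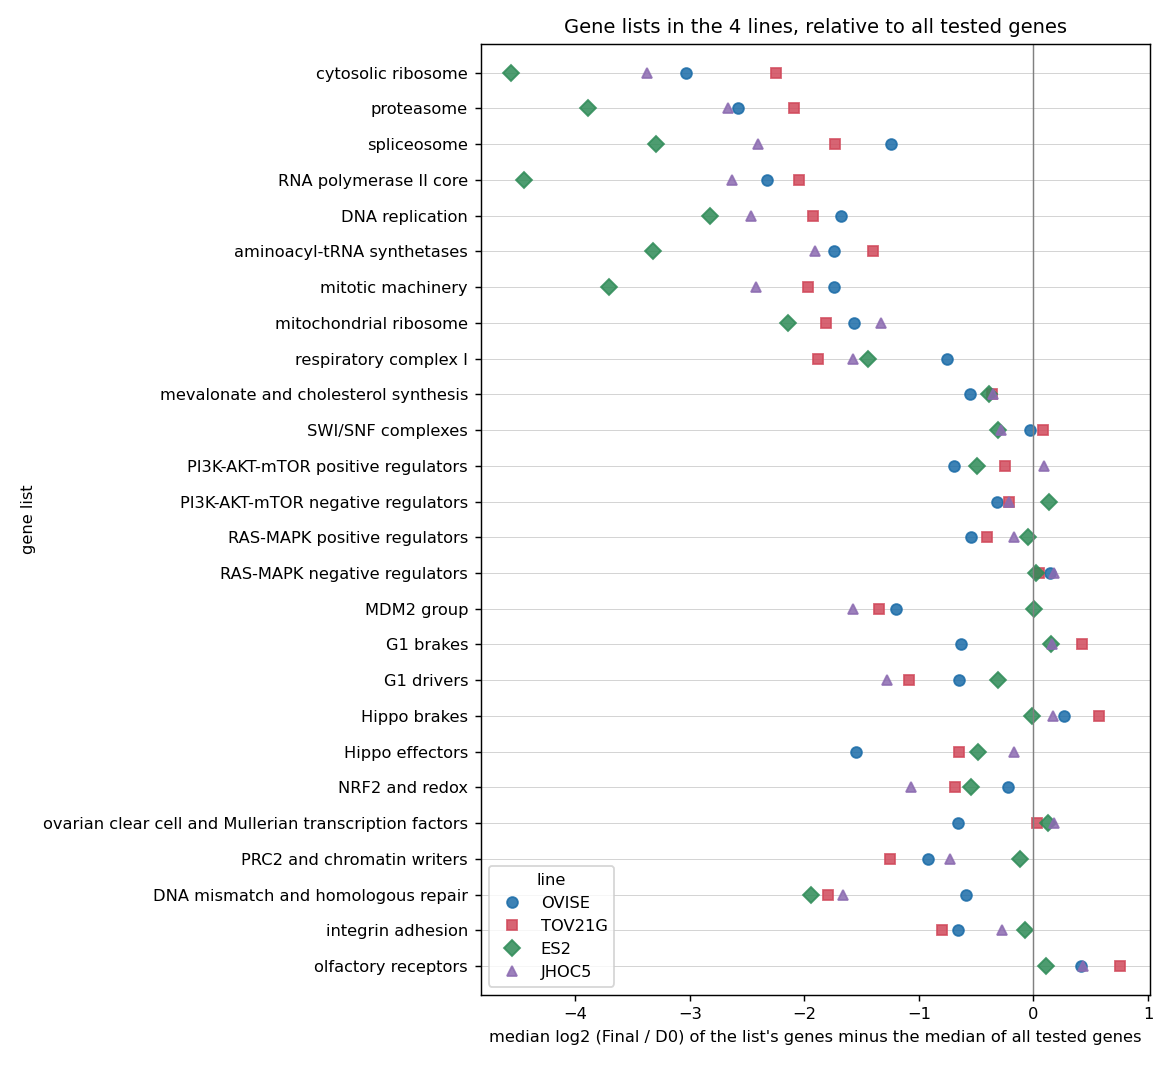
Median log2 Final/D0 of the tested members of each of 26 gene lists, minus the median of all tested genes in that line, with 1 point per line. The core lists lie lowest in ES2 (cytosolic ribosome -4.56, against -3.03 in OVISE and -2.25 in TOV21G), and among these relative medians only that of the MDM2 group in ES2, near 0, changes sign with scaling to control or olfactory receptor guides.

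Genes of respiration and sterol synthesis also fell on average. Respiratory complex I (47 genes, relative median -1.58, adjusted p = 2.39e-13) had 2 fallen members, NDUFB10 (-4.09 ± 0.60, adjusted p = 0.0316) among them, and 8 adjusted over the list alone. The mevalonate and cholesterol list (28 genes, -0.61, adjusted p = 0.000789) also had 2, PMVK (-3.44, adjusted p = 0.0290), which phosphorylates mevalonate phosphate, and HMGCS1 (-3.23, adjusted p = 0.0477), which makes HMG-CoA, and 7 adjusted over the list alone. With an estimated correlation that list had an adjusted p = 0.0425, and 19 of the 21 lists past the threshold in the 4-line average still passed. In growth signalling, MTOR, the kinase at the centre of nutrient sensing, fell (-3.29 ± 0.20, adjusted p = 0.0342), 1 of 29 positive regulators of PI3K, AKT and mTOR both over all genes and adjusted over the list alone. That list as a whole (-0.46, adjusted p = 0.0326) had an adjusted p = 0.0987 with an estimated correlation. GRB2, the adaptor between growth factor receptors and RAS, was the 1 of 30 positive regulators of RAS and MAPK to fall (-3.23 ± 0.09, adjusted p = 0.0371), and the 1 adjusted over the list alone. Its values were -3.82 in OVISE, -3.95 in TOV21G, -0.27 in ES2 and -4.89 in JHOC5, and the list had an adjusted p of 0.102 (-0.25). Among 18 drivers of G1 (-0.88, adjusted p = 1.11e-07), CDK4, a kinase that phosphorylates RB1 (-3.42, adjusted p = 0.0441), and CCNA2, cyclin A2 (-2.71, adjusted p = 0.0471), fell, 2 over all genes and 4 adjusted over the list alone.

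Of the other lists, several moved as groups with 0 single members past the edgeR test over all genes. The DNA mismatch and homologous repair list (22 genes, relative median -1.66, adjusted p = 1.73e-09) had 6 members below the threshold adjusted over the list alone. Its lowest were WEE1, the kinase that holds back CDK1 (-3.74, adjusted p = 0.192), and RAD51D, a factor of homologous recombination (-3.31, adjusted p = 0.0802). The 5 genes of the MDM2 group (MDM2, MDM4, PPM1D, USP7 and TERF1) fell as a list (-0.80, adjusted p = 0.0005, 1 adjusted over the list alone). MDM2, a ubiquitin ligase, had -3.33 in OVISE, -3.22 in TOV21G, 0.03 in ES2 and -3.98 in JHOC5, and USP7 averaged -1.64. Before subtraction of the all-gene median the medians of the G1 brakes and of the negative regulators of RAS and MAPK were under 0, while their tests pointed up. The 23 brakes of Hippo signalling lay higher than other genes (0.43, adjusted p = 0.00225), about where the olfactory receptors lie (0.40), and the 6 Hippo effectors fell (-0.92, adjusted p = 0.000897), with 0 members of either adjusted over the list alone. Before the all-gene median was taken off, the median of the brakes changed sign with either guide-based scaling. TEAD1, a DNA-binding partner of YAP1, averaged -2.37 and YAP1 itself -1.34, while WWC2 and MOB1B among the brakes both had -0.67. NRF2 and redox genes (23, -0.74, adjusted p = 0.000701) and PRC2 and chromatin writers (23, -0.78, adjusted p = 0.00119) fell as lists with 0 members adjusted over the list alone. GPX4, which detoxifies lipid peroxides, averaged -3.71 and CUL3 -3.11, HDAC3 -2.26 and BRD2 -2.20.

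The 25 integrin adhesion genes (relative median -0.28, adjusted p = 0.0326) had an adjusted p = 0.0534 with an estimated correlation and 0 called members either way, with CDC42 at -2.35 and ILK at -2.12. No direction passed the test for the 29 SWI/SNF subunits (-0.15, adjusted p = 0.633), the 18 negative regulators of PI3K, AKT and mTOR (-0.24, adjusted p = 0.390), the 17 of RAS and MAPK (0.03, adjusted p = 0.534), the 11 brakes of G1 (0.20, adjusted p = 0.468) or the 19 ovarian clear cell and Mullerian transcription factors (-0.04, adjusted p = 0.587). Adjusted over the list alone, SWI/SNF had 1 member lower and 1 higher and the other 4 lists 0, against 0 over all genes tested in each of the 5. Among their largest values were ACTL6A -3.31 and SMARCB1 -1.98 in SWI/SNF, PPP2R2A -2.67 and TSC1 -1.29, NF1 -1.37 and ERRFI1 -0.83, LIN52 -1.90 and FBXW7 -1.28, and VHL -3.26. The 318 olfactory receptor genes, which these cells have no known use for, rose relative to other genes (0.40, adjusted p = 7.18e-06) with 0 called members over all genes or adjusted over the list alone, and their median before subtraction changed sign with either guide-based scaling. Guides against EGFP, LacZ and luciferase, which cut no human gene, had medians of 0.42 in OVISE, -0.11 in TOV21G, 0.60 in ES2 and 0.98 in JHOC5. The shift from olfactory receptor guides to these 137 controls was 0.45 in ES2 (95% interval 0.317 to 0.590) and 0.60 in JHOC5 (0.416 to 0.777), and its interval spanned 0 in OVISE (-0.146 to 0.406) and TOV21G (-0.474 to 0.219).

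By the guide-based edgeR test, ES2 gave the most calls of the lines tested by themselves, with 511 genes depleted and 22 enriched. The lowest were RNGTT, the enzyme that caps messenger RNA (-6.88 ± 0.46, adjusted p = 0.00179), TBCA, a tubulin folding cofactor (-6.69 ± 1.09, adjusted p = 0.00555), IMP3, a factor of ribosomal RNA processing (-6.58 ± 0.29, adjusted p = 0.00194), and POLR1B, a subunit of RNA polymerase I (-6.54 ± 0.40, adjusted p = 0.00131). PSMA5 of the proteasome (-6.46, adjusted p = 0.00218) and FTSJ3, a ribosome biogenesis methyltransferase (-6.45, adjusted p = 0.00674), came next. Enriched genes moved by less, led by ASTN1, a neuronal adhesion protein (1.55 ± 0.44, adjusted p = 0.0424), SYCP2, a protein of meiotic chromosomes (1.41 ± 0.06, adjusted p = 0.0486), TOX3 (1.32, adjusted p = 0.0269) and C6orf10 (1.32, adjusted p = 0.0176). CFI, complement factor I, rose by 1.24 (adjusted p = 0.0340) and ENGASE, a cytosolic glycosidase, by 1.17 (adjusted p = 0.0120). Both Final libraries lay below both D0 libraries in each of the 511 depleted genes and above in 21 of the 22 enriched genes, which follows largely from how they were chosen. Over all tested genes the shares in ES2 were 23.8% and 22.6%, against 16.7% by chance. The medians were -4.05 for depleted and 1.03 for enriched genes. The 511 genes had medians of -2.19 in OVISE, -2.75 in TOV21G and -2.63 in JHOC5, with 94.3%, 96.9% and 97.3% of them under 0, against 58.3%, 73.1% and 55.0% of all tested genes. At an unadjusted p under 0.05 there were 1509 genes lower and 583 higher. Without ES2 D0 replicate 2, 339 genes were depleted, 13 enriched and 18 of the 38 named calls past the threshold, and without ES2 D0 replicate 1, 12 genes were enriched and 31 named calls kept. Of the named calls, 29 passed without ES2 Final replicate 1 and 24 without ES2 Final replicate 2. With counts summed per gene, edgeR called 258 genes depleted and 0 enriched in ES2, fewer than in TOV21G (389 and 2897). On the libraries of each line alone, summed counts called more in ES2 (1306 and 69) than in TOV21G (0 and 0). The 12 and 13 enriched genes without a D0 library share 4 and 2 with the 22.

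All 8 core lists fell in ES2, and the cytosolic ribosome most (relative median -4.56, camera adjusted p = 2.12e-93). With an estimated correlation the ribosome had an adjusted p = 4.75e-05, and 15 of the 16 lists past the threshold in ES2 still passed. Of the 39 ribosome genes 26 fell over all genes and 37 adjusted over the list alone. The matching counts were 18 and 29 of 32 for the proteasome (-3.89), 16 and 30 of 38 for the spliceosome (-3.30), 6 and 9 of 11 for RNA polymerase II (-4.45) and 17 and 31 of 44 for DNA replication (-2.83). They were 7 and 18 of 20 for aminoacyl-tRNA synthetases (-3.32), 20 and 34 of 42 for the mitotic machinery (-3.70) and 14 and 37 of 72 for the mitochondrial ribosome (-2.14). In sterol synthesis 7 of 28 genes fell and 9 adjusted over the list alone (-0.39, adjusted p = 7.95e-07, and 0.00902 with an estimated correlation). Among them were MBTPS2 (-6.07 ± 1.36, adjusted p = 0.00219), MBTPS1 (-3.96, adjusted p = 0.0433) and SCAP (-4.17, adjusted p = 0.0166), which act in the release of the sterol-regulated transcription factors SREBF1 and SREBF2 from the membrane, and HMGCS1 (-5.16, adjusted p = 0.00986). Complex I (-1.45, adjusted p = 4.64e-13) had 4 fallen genes and 13 adjusted over the list alone, with NDUFA11 at -3.56 (adjusted p = 0.00593), NDUFS1 at -3.15, NDUFB9 at -2.97 and NDUFB10 at -2.74. The positive regulators of PI3K, AKT and mTOR (-0.49, adjusted p = 0.000137) had an adjusted p = 0.0167 with an estimated correlation. Of these genes 4 fell over all genes and adjusted over the list alone. They were MTOR (-4.43, adjusted p = 0.0152), the cap-binding protein EIF4E (-4.14), LAMTOR5 (-4.04) and RRAGC (-2.62). The last 2 are parts of the lysosomal platform that recruits mTOR.

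Single genes of the cell cycle and of other lists also fell in ES2. In the G1 drivers (-0.31, adjusted p = 6.8e-07), CCND1, cyclin D1 (-5.30 ± 0.38, adjusted p = 0.00555), its partner CDK4 (-5.02 ± 0.92, adjusted p = 0.0108), CCNA2 (-4.69, adjusted p = 0.00365) and CDK7 (-3.47, adjusted p = 0.0307) fell, 4 of 18 by either adjustment. LIN52, listed as a brake of G1 but also part of a complex that turns on mitotic genes, fell (-2.99, adjusted p = 0.00986), 1 of 11 by either adjustment, and the list had an adjusted p of 0.704 (0.15). MAP2K1, the MAPK kinase MEK1, fell (-2.23 ± 0.24, adjusted p = 0.00549), 1 of 30 in its list, with 4 lower and 1 higher adjusted over the list alone and an adjusted p of 0.538 for the list (-0.05). YAP1, the Hippo effector, fell (-4.03 ± 0.45, adjusted p = 0.0209), 1 of 6 by either adjustment. The effectors as a list (-0.48, adjusted p = 0.00652) had an adjusted p = 0.0546 with an estimated correlation. MAP4K4, a kinase upstream of the Hippo core, rose (1.16, adjusted p = 0.0269), 1 of 23 brakes by either adjustment (-0.01, where the test pointed up, adjusted p = 0.0736). WEE1 (-4.57, adjusted p = 0.0370) and RAD51D (-3.49, adjusted p = 0.0102) were the 2 of 22 repair genes that fell (-1.94, adjusted p = 1.09e-12, 8 adjusted over the list alone). SOD1 (-3.41, adjusted p = 0.0372) and PRDX1 (-3.23, adjusted p = 0.0227), enzymes that remove superoxide and peroxide, were 2 of 23 redox genes (-0.54, adjusted p = 0.000105, 4 adjusted over the list alone). VHL, the ligase subunit that marks hypoxia-inducible factors (-4.46, adjusted p = 0.0207), and PGR, the progesterone receptor (-3.59, adjusted p = 0.0404), were 2 of 19 in the transcription factor list by either adjustment (0.13, adjusted p = 0.752).

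The remaining lists in ES2 had 0 called members over all genes except the 318 olfactory receptors, of which 2 rose over all genes and 0 adjusted over the list alone (0.11, adjusted p = 0.0138). PRC2 and chromatin writers had 1 member lower and 1 higher adjusted over the list alone (-0.12, adjusted p = 0.957), with HDAC3 at -3.35 and BAP1 at -2.25. SWI/SNF (-0.31, adjusted p = 0.709, ACTL6A -3.39 and DPF2 -1.79), the negative regulators of PI3K, AKT and mTOR (0.14, adjusted p = 0.421, PPP2R2A -2.18 and TBC1D7 0.92) and those of RAS and MAPK (0.02, adjusted p = 0.538, PEA15 -1.49) had none. Integrin adhesion (-0.07, where the test pointed up, adjusted p = 0.824, CDC42 -1.76) and the MDM2 group (adjusted p = 0.889) also had none. Before the all-gene median was taken off, the medians of the lists above 0 in ES2 changed sign with scaling to control or olfactory receptor guides.

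OVISE and TOV21G each had 0 genes past the adjusted threshold in either direction by edgeR. The core lists were lower than other genes in both lines, but in TOV21G no core list passed with an estimated correlation (adjusted p of 0.0501 to 0.127). In OVISE 682 genes were lower and 509 higher at an unadjusted p under 0.05, and in TOV21G 603 and 496. The DESeq2 Wald test called 1 depleted gene in OVISE and 0 in TOV21G, and counts summed per gene with edgeR called 0 depleted genes in OVISE and 389 depleted and 2897 enriched in TOV21G. Scaled on the sums these became 452 and 286, and on the TOV21G libraries alone 0 and 0, where the guide-based test called 5 and 1. On the OVISE libraries alone summed counts called 21 depleted genes. The smallest adjusted p was 0.177 in OVISE and 0.363 in TOV21G. Without OVISE D0 replicate 2, 1 gene was called depleted in OVISE, and without TOV21G Final replicate 1, 1 in TOV21G. In simulated data with a known change of -4 on the log2 scale, the test recovered 42.9% of changed genes in OVISE and 35.7% in TOV21G, against 100% in ES2. The simulation gave each line the same spread at D0 and Final. In the real TOV21G libraries the control guides differed between replicates with an SD of 0.53 at D0 and 3.38 at Final, so the 35.7% need not hold there. The 298 core genes had relative medians of -1.83 in OVISE, -1.87 in TOV21G, -3.27 in ES2 and -2.22 in JHOC5, and 57.4%, 54.0%, 89.9% and 66.4% of them lay in the lowest 10% of genes of the line.

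In OVISE the 8 core lists fell, led by the cytosolic ribosome (relative median -3.03, adjusted p = 4.27e-15, 0 members over all genes and 12 adjusted over the list alone), and complex I fell as well (adjusted p = 0.0004, with NDUFA13 at -4.57). PIK3CA, the catalytic subunit of PI3K that is often mutated in clear cell carcinoma, had -4.89 ± 1.28 in OVISE (adjusted p = 0.177), against 0.51 in TOV21G, 0.28 in ES2 and -0.31 in JHOC5. Its list (adjusted p = 0.0394) had an adjusted p = 0.132 with an estimated correlation, and PIK3CA was the 1 member past the threshold adjusted over the list alone. The Hippo effectors fell as a list (-1.55, adjusted p = 0.000643, 0 over all genes and 1 adjusted over the list alone), with TEAD1 at -4.16 and WWTR1, the paralogue of YAP1, at -2.71. KLF5 (-4.36) and PAX8 (-4.32), epithelial and Mullerian transcription factors, were the 2 members of their list past the threshold adjusted over the list alone, against 0 over all genes (list adjusted p = 0.0599). PRC2 and chromatin writers fell as a list (-0.92, adjusted p = 0.0182), with EED at -2.86. The MDM2 group (adjusted p = 0.00365, MDM2 -3.33 and USP7 -2.68) had an adjusted p = 0.056 with an estimated correlation, the G1 drivers (0.0182, MYC -4.34) 0.115 and the repair list (0.0239, BRCA2 -3.49) 0.0639 in the same test.

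In TOV21G 15 lists passed camera with the preset correlation and 0 with an estimated one. The cytosolic ribosome (relative median -2.25, adjusted p = 1.04e-07) had an adjusted p = 0.067 with an estimated correlation, and complex I (-1.88, adjusted p = 1.1e-05) an adjusted p = 0.0501 with an estimated correlation. NDUFB10 had -5.85 and TIMMDC1, a complex I assembly factor, -5.44, and 3 of 47 complex I genes were past the threshold adjusted over the list alone, against 0 over all genes. The lowest values included CDC45 (-6.57, adjusted p = 0.499), PMVK (-6.23 ± 0.60, adjusted p = 0.363) and BRD2, a bromodomain protein (-5.23, adjusted p = 0.499). CDK4 had -4.82 and its relative CDK6 -3.19. On the positive side stood the growth-restraining genes RB1 (2.85 ± 0.87, adjusted p = 0.612) and NF2 (2.62 ± 0.67, adjusted p = 0.596). The Hippo brakes (0.58, adjusted p = 0.0113), to which NF2 belongs, had an adjusted p = 0.0501 with an estimated correlation. The median of the Hippo brakes before subtraction was under 0 and changed sign with DESeq2 size factors. Over the 15 lists the adjusted p with an estimated correlation ran from 0.0501 to 0.137.

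JHOC5 had 1 library per time, so its values have no replicate check and no test. The lowest were BUB3 (-7.11), the ribosome biogenesis genes ISG20L2 (-6.89) and NOP58 (-6.75), POLR1B (-6.68) and RNASEH2A, the catalytic subunit of ribonuclease H2 (-6.61). The highest were CAMTA2 (2.65), PIWIL2, a piRNA-binding protein of the germ line (2.38), EHBP1 (2.36), RASGRF1, an exchange factor for RAS (2.26), and FAM50B (2.15). Across genes, which are not independent replicates, the changes in JHOC5 correlated with those in ES2 at a Pearson's r of 0.637 (Spearman's rho 0.386), the highest r of the 6 pairs of lines, while rho was highest between TOV21G and JHOC5 (0.400). The lowest of both was 0.356 (0.267) between OVISE and TOV21G. Control guides spread less in ES2 and JHOC5 than in OVISE and TOV21G, and noise lowers such correlations. The order of the pairs therefore need not reflect how alike the lines are.

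The change of 14 genes differed between lines by the test of the difference itself, 13 of them in ES2 against the mean of OVISE and TOV21G. FGF4, a fibroblast growth factor, was lower in ES2 by the clearest margin (difference -4.84 ± 0.86, adjusted p = 0.000319), with -4.93 in ES2 and 0.14, -0.32 and 0.78 in OVISE, TOV21G and JHOC5. MBTPS2, a membrane protease that activates the sterol-regulated SREBF factors, differed by -6.41 ± 1.54 (adjusted p = 0.00771, 3 guides), with -6.07 in ES2, -0.78 in OVISE, 1.47 in TOV21G and -1.21 in JHOC5. The splicing factor PRPF19 (-4.91, adjusted p = 0.00771), the replication clamp PCNA (-4.57, adjusted p = 0.0389), the unfoldase VCP (-4.32, adjusted p = 0.0389) and topoisomerase TOP2A (-4.22, adjusted p = 0.0389) were lower in ES2 too. So were WNK1, a kinase that controls chloride transport (-3.84, adjusted p = 0.0473), and LYRM4, needed to build iron-sulfur clusters (-2.94, adjusted p = 0.0154). CPOX, an enzyme of haem synthesis (3.12, adjusted p = 0.0478), CHUK, a kinase of the NF-kappaB pathway (2.79 ± 0.28, adjusted p = 0.0473), and ZNHIT3 (2.35, adjusted p = 0.0407) were higher in ES2 than the mean of OVISE and TOV21G. CHUK had -0.74 in OVISE, -4.43 in TOV21G and 0.20 in ES2, so most of its difference came from the low value in TOV21G. BRAF, a kinase of the MAPK pathway, differed by -4.50 without passing (adjusted p = 0.0936) and is named after its values were seen. In OVISE, CDC45 was higher than in TOV21G and ES2 (5.51 ± 1.03, adjusted p = 0.0398), with -0.67 in OVISE, -6.57 in TOV21G, -5.79 in ES2 and -3.75 in JHOC5. PIK3CA differed by -5.28 ± 1.29 in OVISE without passing (adjusted p = 0.273).

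No gene differed in TOV21G (0 by edgeR, with 500 lower and 497 higher at an unadjusted p under 0.05, 0 by the DESeq2 Wald test and 0 by counts summed per gene), and 1 did without ES2 Final replicate 2. The 13 genes that differed in ES2 became 1 without TOV21G Final replicate 2, 2 without OVISE D0 replicate 2, 4 without OVISE D0 replicate 1, 5 without TOV21G D0 replicate 1 or ES2 D0 replicate 2, 6 without TOV21G Final replicate 1 or TOV21G D0 replicate 2, and 33 without ES2 Final replicate 2. FGF4 kept its call without any single library and lost it with counts summed per gene under either scaling (adjusted p of 1.32e-05 to 0.237 over 23 settings), and MBTPS2 lost it with the same summed counts and without OVISE D0 replicate 2 or TOV21G Final replicate 2 (0.0025 to 0.237). Of the same 23 settings, PRPF19 kept its call in 16, PCNA in 15, LYRM4 in 14, TOP2A in 12, VCP in 11, WNK1 in 10, ZNHIT3 in 9, CHUK in 6 and CPOX in 3 (adjusted p up to 0.956). With JHOC5 in the mean of the other lines, 4 of the 11 named differences in ES2 lost their call, namely PCNA, VCP, LYRM4 and CPOX. CDC45 in OVISE lost its call without OVISE D0 replicate 1, OVISE Final replicate 1, OVISE D0 replicate 2, either TOV21G Final library or either ES2 library of replicate 2. It also lost it with the replicate block, control scaling, counts summed per gene under either scaling and JHOC5 in the mean of the other lines, with an adjusted p of 0.00851 to 0.6.

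Lists differed between lines as well. Relative to all genes, the cytosolic ribosome (-1.69, adjusted p = 7.25e-10), spliceosome (-1.43, adjusted p = 1.06e-07), RNA polymerase II (-2.33), aminoacyl-tRNA synthetases (-1.77, adjusted p = 8.75e-08) and mitotic machinery (-1.32) fell further in ES2 than in OVISE and TOV21G. PRC2 and chromatin writers were higher there (0.81, adjusted p = 0.0025). These 6 lists had an adjusted p of 0.0211 to 0.0378 with an estimated correlation. The proteasome (-1.51, adjusted p = 2.16e-06) had an adjusted p = 0.0613 with an estimated correlation, DNA replication (-0.99, adjusted p = 0.000383) an adjusted p = 0.0747 with an estimated correlation, and the MDM2 group (1.05, adjusted p = 0.00452) an adjusted p = 0.0828 with an estimated correlation. In OVISE the ribosome (0.80, adjusted p = 0.00152) had an adjusted p = 0.333 with an estimated correlation, and the spliceosome (0.97), DNA replication (0.55) and mitotic machinery (1.05) an adjusted p = 0.322 with an estimated correlation. In TOV21G the ribosome (0.92), proteasome (1.40), RNA polymerase II (1.34) and aminoacyl-tRNA synthetases (0.98) had an adjusted p = 0.233 with an estimated correlation.

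**Figure D3:**
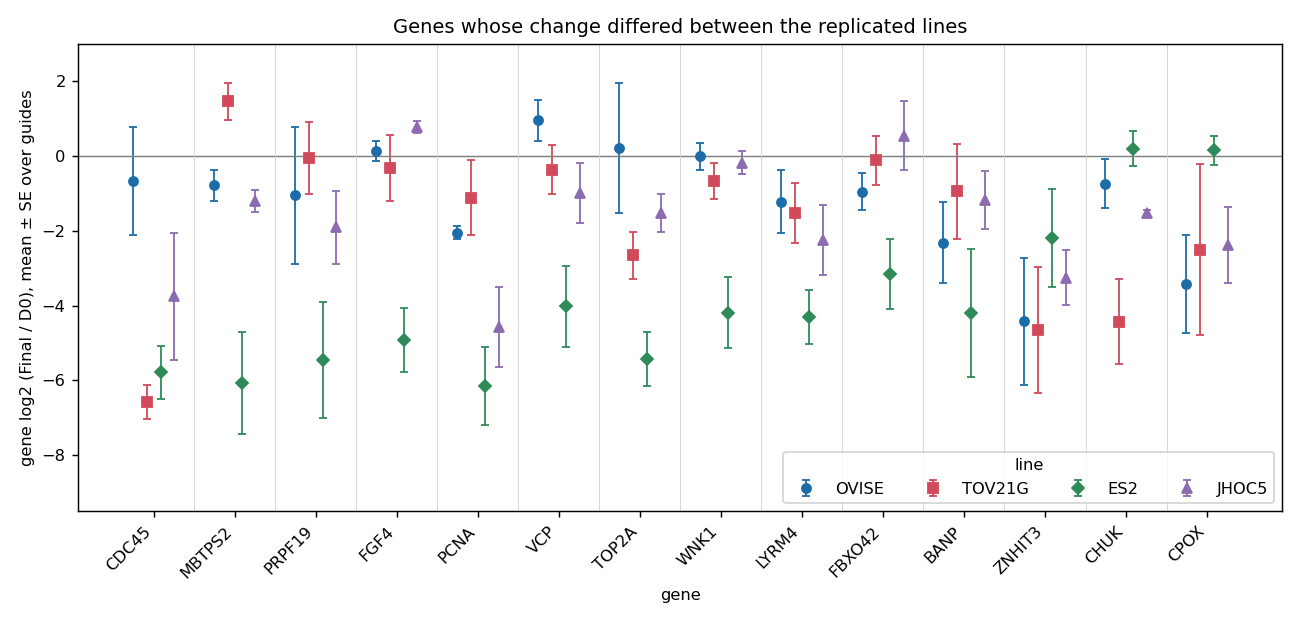
Mean log2 Final/D0 over guides (± SE over guides) in each line for the 14 genes whose change differed between lines. FGF4 is at -4.93 in ES2 and between -0.32 and 0.78 in the other lines, and CDC45 is at -0.67 in OVISE and between -6.57 and -3.75 elsewhere.

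CCND1, FGF4, YAP1 and PGR lie on chromosome 11 in 2 stretches of neighbouring genes that were low in ES2. The median of the 10 tested neighbours of FGF4 was -2.51 in ES2, against -0.06 in OVISE, -0.31 in TOV21G and -0.66 in JHOC5, and that of the 10 neighbours of YAP1 was -1.27, against -0.42, 0.38 and 0.11. Next to CCND1 and FGF4, ORAOV1, a ribosome-associated factor, had -5.45 (with -4.26 in OVISE, -2.75 in TOV21G and -2.89 in JHOC5), FGF19 -2.67 (-1.82 in JHOC5), ANO1, a chloride channel, -2.04 (-2.66 in TOV21G), FADD, an adaptor of death receptors, -2.44, and CTTN, an actin-binding protein, -2.28. Near YAP1 and PGR, ARHGAP42 had -3.47 (-2.09 in JHOC5), C11orf70 -3.14 and ANGPTL5, a secreted protein, -2.76. These neighbours were chosen after their values were seen. Of the 511 genes depleted in ES2, 7 are FGF4, YAP1 or 1 of their 10 tested neighbours each (ANO1, C11orf70, CCND1, FGF4, ORAOV1, PGR and YAP1). Farther out ARHGAP42 was called (adjusted p = 0.0343). MRPL21 was called too (-4.02, adjusted p = 0.00921), but it was as low in OVISE (-4.35) and is parted from the low stretch by IGHMBP2 (0.04), MRGPRD (-0.18) and MRGPRF (0.05).

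**Figure D4:**
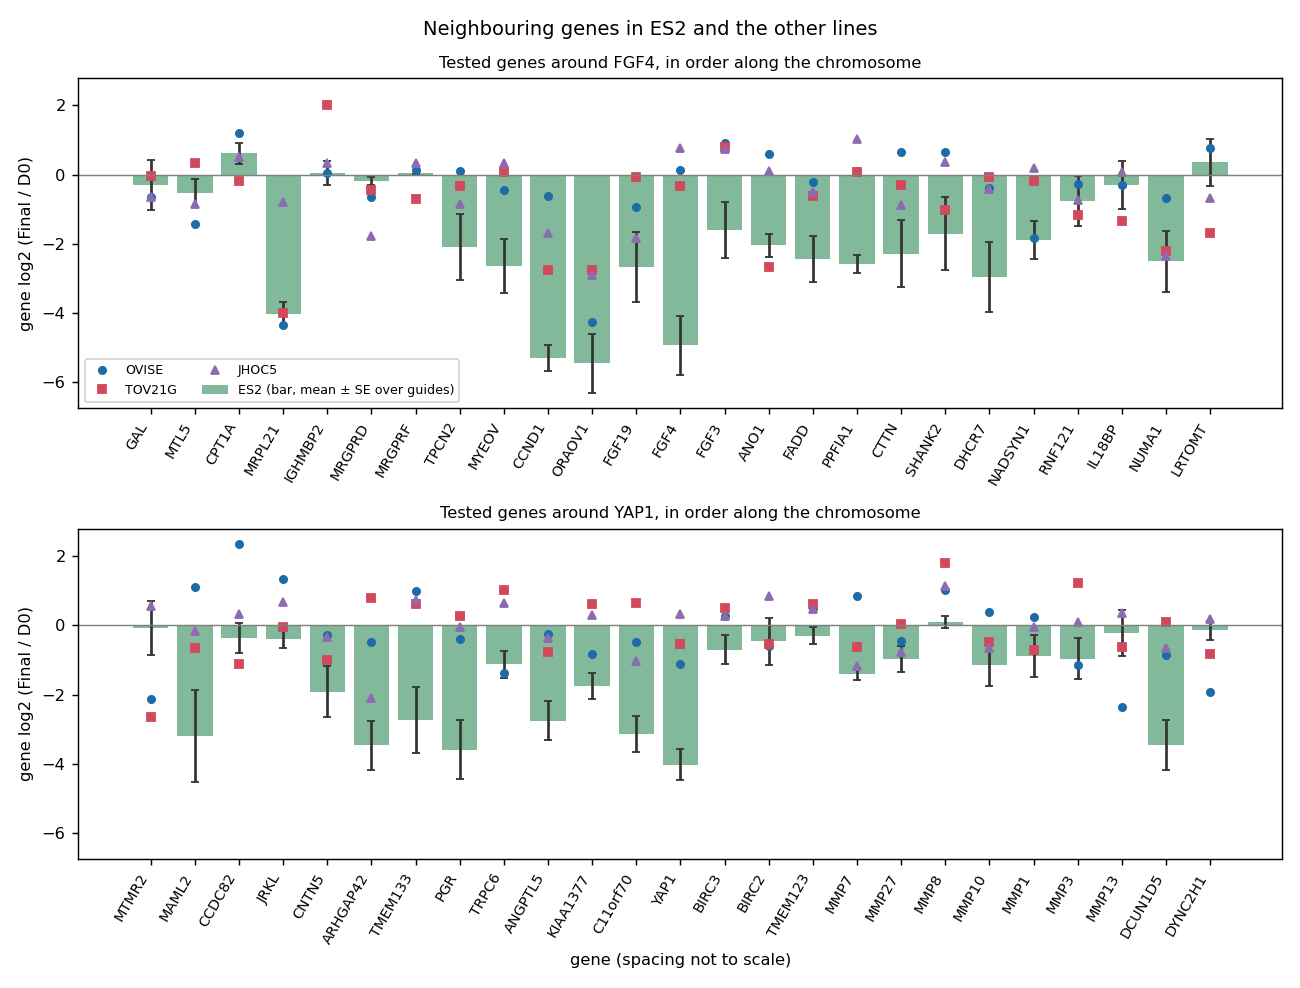
Log2 Final/D0 of 25 tested genes each in chromosomal order around FGF4 and around YAP1, with ES2 as bars (± SE over guides) and the other lines as points. CCND1 (-5.30), ORAOV1 (-5.45) and FGF4 (-4.93) are lowest in the stretch around FGF4, and YAP1 (-4.03) and PGR (-3.59) in the stretch around YAP1.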

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

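The tests of extra copies, of a need for CCND1 and YAP1 alone and of generally harmful guides in the stretches on chromosome 11, and those of guide loss by chance and of weaker selection, were chosen only after the result was seen; the splits of the libraries and the thinning of reads were planned.

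The change of 14 genes differed between lines by a test of the difference itself, given here as the log2 fold change (± SE over guides) in a line minus the mean of the other 2 replicated lines. In ES2, MBTPS2 differed by -6.411 ± 1.54, and PRPF19 by -4.907 ± 0.805. FGF4 differed by -4.84 ± 0.857, and PCNA by -4.574 ± 1.02. VCP differed by -4.316 ± 0.88, TOP2A by -4.219 ± 0.769, and WNK1 by -3.842 ± 1.05. LYRM4 differed by -2.941 ± 1.32 with 3 of 4 guides that way. FBXO42 (-2.61 ± 0.471, adjusted p = 0.0407) and BANP (-2.57 ± 2.31, adjusted p = 0.0389) lie outside the rule for named genes and were chosen after their values were seen. ZNHIT3 differed by 2.345 ± 1.53, CHUK by 2.786 ± 0.284 and CPOX by 3.116 ± 1.35. CDC45 differed by 5.505 ± 1.03 in OVISE. In ES2 the 13 calls became 1 without TOV21G Final replicate 2, 2 without OVISE D0 replicate 2, 4 without OVISE D0 replicate 1, 5 without TOV21G D0 replicate 1 or ES2 D0 replicate 2, 6 without TOV21G Final replicate 1 or D0 replicate 2 and 33 without ES2 Final replicate 2. CDC45 had no call without OVISE D0 replicate 1, OVISE Final replicate 1, OVISE D0 replicate 2, either TOV21G Final library or either ES2 library of replicate 2, nor with the replicate block, control scaling, counts summed per gene under either scaling or JHOC5 in the mean of the other lines. FGF4 had no call with counts summed per gene under either scaling.

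For the number of genes depleted on average, a chance division of the libraries is argued against, in the additive model only. Of 50 splits of the 14 libraries into 7 and 7 with the line in the model, 1, the real one, gave as many depleted genes (178 in that model, highest other 1), and 1 gave as many enriched genes (10, highest other 1, the larger of the 2 directions of a split being taken). These 10 share 0 with the 3 genes enriched in the 4-line average, for which the splits therefore decide nothing. Of the other splits, 44 called none. Splits that mix D0 and Final leave the change between them in the spread, which lowers their counts. Of the 178 depleted genes of that model, 104 were among the 164 of the 4-line average, so the splits do not bear on which genes were called.

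In ES2, genes that lie next to each other on chromosome 11 were low around FGF4 and CCND1 and around YAP1 and PGR, of which FGF4 and YAP1 were taken as centres because they were called. Among 17269 neighbourhoods of 10 genes, the median of the neighbours of FGF4 (-2.51) lay in the lowest 0.0405% and that of the neighbours of YAP1 (-1.27) in the lowest 0.44%, although 0 of them belong to a core list. Guides that harm any cell are argued against, since the median over both groups of neighbours lay at the 36.9 percentile or higher in OVISE, TOV21G and JHOC5 (by stretch, the lowest were 8.45 for the neighbours of FGF4 in JHOC5 and 29.3 for those of YAP1 in OVISE). A need for CCND1 and YAP1 alone would leave their neighbours like other genes, whose median was 0.03. The 9 neighbours of FGF4 without CCND1 had a median of -2.44 (95% interval -2.67 to -2.04), at a percentile of 0.0405. The 10 of YAP1 had one of -1.27 (-3.14 to -0.47), at a percentile of 0.44. These intervals treat adjacent genes as separate draws. An earlier bound, most neighbours in the lowest 5% of all genes, was not reached (11.1% and 30%) and was replaced after that was seen. Such a need leaves the low neighbours without an account. They are the pattern that prompted the test, however, so the test cannot decide against it. Cutting of a region present in extra copies in ES2, which harms cells whatever the gene does, stays open, as does a need for CCND1 or YAP1 on top of it, because low neighbours (0.44) are the pattern itself and no copy number data were used here.

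OVISE and TOV21G had 0 called genes by the guide-based edgeR test (682 and 603 genes lower at an unadjusted p under 0.05, 1 and 0 called depleted by the DESeq2 Wald test) where ES2 had 511 depleted. Summed counts called 0, 389 and 258 depleted in OVISE, TOV21G and ES2. Scaled on the sums these were 0, 452 and 266, and on the libraries of each line alone 21, 0 and 1306. TOV21G thus had more calls than ES2 in 2 of these 3 fits. The causes weighed here concern the 0 calls of the guide-based test in OVISE and TOV21G. Fewer reads are argued against as the cause, since ES2 libraries thinned to 7234046 reads, the smallest effective size in those lines, still gave 491 depleted genes. Loss of guides by chance between D0 and Final, when few cells carry each guide, is a candidate explanation in TOV21G, where the SD of control guides between replicates rose 6.38 times (95% interval 5.12 to 7.98 over guides) from D0 to Final. In OVISE the SD of control guides between replicates was as large at D0 (2.88) as at Final (2.76, a ratio of 0.96, interval 0.806 to 1.14). A spread as wide was thus there at D0. Over all guides the replicate differences at D0 and at Final correlated at 0.0132, so the spread at Final is not shown to be that of D0 carried on. Whether guides were lost later in OVISE stays open. Weaker selection in the same time may play a part in both lines, since core genes fell, relative to all tested genes, by at most 0.573 of their fall in ES2. That ratio cannot tell weaker selection from loss of guides. Before subtraction of the all-gene median, the mitochondrial ribosome had a lower median in TOV21G (-2.50) than in ES2 (-2.11), as did complex I (-2.56 and -1.41). The other core lists were all lower in ES2. A biological difference between the lines stays open and untested.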

How the results depend on the processing

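Leaving out TOV21G, leaving out TOV21G and OVISE, and summed counts with their own scaling or own libraries were tests chosen only after the results were seen; the other alternatives were planned. None of the named calls reversed in the alternatives run on them, while in TOV21G the balance of lower and higher genes turned with summed counts (below). Of the 29 named calls of the 4-line average 0 held in all 26 settings, of the 38 in ES2 10 held in all 16 (CCNA2, CCND1, CDK4, HMGCS1, IMP3, MAP2K1, MBTPS2, POLR1B, PSMA5 and TBCA), and of the 11 named differences in ES2 and the 1 in OVISE 0 held in all 23. Of 262 named values not called, 66 passed the threshold in at least 1 setting. Whether the replicate numbers pair the samples was not settled. The differences between replicates 1 and 2 at D0 and at Final correlated across guides at 0.0132 in OVISE, -0.00148 in TOV21G and 0.0635 in ES2. Noise at either time lowers such a correlation, so values near 0 cannot show that the samples are unpaired. The replicate block serves only as an alternative. Depth limited the calls little in ES2, where thinning to 7234046 reads, the effective size of TOV21G Final replicate 1, gave 491 depleted and 23 enriched genes against 511 and 22.

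The 164 genes depleted on average became 47 with control scaling, 86 with olfactory receptor scaling, 547 with summed counts, 845 with summed counts scaled on the sums, 256 with the replicate block, 67 without JHOC5 and 315 without TOV21G and OVISE. Without TOV21G there were 221, of which 108 were among the 164. Leaving out single libraries gave 15 (without TOV21G Final replicate 1) to 285 (without ES2 Final replicate 2). The count of 3 enriched genes became 0 with control and with olfactory receptor scaling, 1 with the minimum of 100 reads, 88 with summed counts, 54 with summed counts scaled on the sums, 9 with the block, 1 without JHOC5, 10 with the additive model, 13 without TOV21G and 22 without TOV21G and OVISE, and single libraries gave 0 (without OVISE Final replicate 1 or 2) to 10 (without ES2 Final replicate 1). The sets with summed counts under either scaling, the additive model, and without JHOC5, TOV21G, or TOV21G and OVISE hold 0 of the 3 genes.

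In OVISE the 0 depleted genes (682 at an unadjusted p under 0.05 by edgeR) became 1 with the DESeq2 Wald test and 21 with summed counts on its own libraries, and single libraries gave 0 to 1 (without OVISE D0 replicate 2). In TOV21G the 0 depleted and 0 enriched genes (603 and 496 unadjusted) became 389 and 2897 with summed counts, 452 and 286 with summed counts scaled on the sums, 0 and 0 with summed counts on its own libraries and 5 and 1 with the guide-based test on them, and single libraries gave 0 to 1 depleted (without TOV21G Final replicate 1). The fall from 2897 to 286 came with the scaling alone, which is the only choice that differs between the 2 fits. In ES2 the 511 depleted and 22 enriched genes became 258 and 0 with summed counts (edgeR), 266 and 0 with these scaled on the sums and 1306 and 69 with summed counts on its own libraries, against 583 enriched genes unadjusted in the rank-based test. With control scaling they were 353 and 17, of which 343 and 7 were among the 511 and 22. TOX3, CFI and ENGASE lost their call there, while ASTN1, SYCP2 and C6orf10 kept it. With olfactory receptor scaling they were 482 and 19, of which 475 and 16 were shared. The guide-based test on the ES2 libraries alone called 22 enriched genes, and 10 of them were among the original 22. Single ES2 libraries gave 339 (without D0 replicate 2) to 440 depleted and 12 (without D0 replicate 1) to 18 enriched, with 13 enriched without D0 replicate 2.

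The 1 gene that differed in OVISE became 0 with control scaling, summed counts under either scaling, the block and JHOC5 in the mean of the other lines, and 2 with the Wald test, and single libraries gave 0 (without any of OVISE D0 1, Final 1 and D0 2, TOV21G Final 1 and 2 and ES2 D0 2) to 3 (without OVISE Final replicate 2). In TOV21G single libraries gave 0 to 1 differing genes (without ES2 Final replicate 2). The 13 in ES2 became 1 with summed counts, 0 with these scaled on the sums and 20 with the block, and single libraries gave 1 (without TOV21G Final replicate 2) to 33 (without ES2 Final replicate 2). With an estimated correlation the 15 lists past the threshold in TOV21G, the 4 that differed in OVISE and the 4 that differed in TOV21G all became 0. The relative median of the core genes in JHOC5 ran from -2.37 to -2.17. For all these changes but that of the summed counts in TOV21G the cause was not tested.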

Other observations

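The 3 tests on the guides read most in JHOC5 D0 were chosen only after the result was seen.

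Some values per line stand outside the lists of the comparisons. In TOV21G, GAL3ST1, which makes sulfated glycolipids, had -2.99 ± 0.42 (adjusted p = 0.363) and CDCA8, a subunit of the chromosomal passenger complex, -5.07, while PFKFB3, an activator of glycolysis, had 2.91 ± 0.26 (adjusted p = 0.499). In OVISE, UBE2M, which transfers NEDD8 to cullins, had -5.02, TOP1, a DNA topoisomerase, -4.05, and SLIT3, a secreted guidance protein, 2.38. None of these passed the test, and all were chosen after their values were seen.

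Among the lowest 15 neighbourhoods specific to a line, all 15 of ES2 lay in the stretches around FGF4 and YAP1 on chromosome 11, whereas the 15 of OVISE came from 8 chromosomes, those of TOV21G from 6 and those of JHOC5 from 9. Neighbourhoods of adjacent genes share members, so they are not separate places. Low neighbourhoods were not limited to ES2. The lowest of TOV21G, around MDGA2 on chromosome 14, had a median of -3.40, with a difference from the other lines of -2.49. That of OVISE, around CHTOP on chromosome 1, had -2.20 (-2.08), and that of ES2, around KIAA1377, -2.75 (-2.89). Of 506 ES2 depleted genes with a known place, 13 lay in the lowest 1% of neighbourhoods, where 5.06 are expected, and 7 of the 13 are FGF4, YAP1 and genes next to them.

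In JHOC5 D0 30 guides held 21.9% of all reads, with 1516916 reads for a guide against CAPN13, and 0.0593% in JHOC5 Final, where that guide had 839 reads. Of the 30 genes they target, 0 were called in the 4-line average by edgeR. Growth of a few JHOC5 clones is argued against by the ratio of the Final share to the D0 share, 0.00271, and an uneven plasmid library by the other D0 libraries, in which the median of the 30 guides was at most 1.76 times the median guide, TOV21G D0 replicate 1 aside. In that library the excess of the 30 guides over TOV21G D0 replicate 2 followed their JHOC5 D0 reads with a rank correlation of 0.982, at a median of 0.474% of those reads (quartiles 0.434% to 0.503%), against at most 0.365 in any other library. A candidate explanation for that excess is that reads of JHOC5 D0 were carried over into TOV21G D0 replicate 1, for example between indexes on a sequencer, while the origin of the 30 high guides in JHOC5 D0 itself stays open.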
